A study of Mus musculus with 12 samples.

How the data were processed

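The series holds 12 RNA sequencing libraries from mouse CD4+ T cells, 3 for each combination of genotype (WT or KKO) and time (24 h or 48 h of activation). Per the submitters' processing notes, reads were checked with FastQC and counted per gene with RSEM against mouse build mm10. The series design text names a human reference in its place, while the organism label, the column headers of the count file and the gene symbols are those of mouse. The RSEM version, the aligner and the gene annotation were not given in the sources used here.

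The deposited file holds RSEM expected counts per gene, unnormalised, as made by the authors. An expected count shares a read among the genes it could come from, so 10.8 to 12.7% of the values in a library were not whole numbers. The file has 32699 gene symbols. Of these, 27 had been turned into dates by a spreadsheet (20 of them tested, 2 called at 24 h and 3 at 48 h), and 1 was named unknown, with at most 2 counts in a library; the date names were not turned back into genes. Another 6 columns of the file were not used here, since no sample label describes them. The 13 mitochondrially encoded genes were not in the file, so RNA quality could not be read from them. Gene positions came from the RefSeq annotation of mouse build GRCm38, which holds 11785 (89.3%) of the tested symbols.

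Totals per library were 17.8 to 32.6 M (mega) counts, and the 10 highest genes held 5.91 to 8.02% of a library. Replicates of a group correlated at Spearman's rho of 0.989 to 0.997 and differed by more than counting noise in every pair (chi-square over degrees of freedom 5.73 to 23.2). CPM (counts per M of library total) used TMM-scaled library sizes. Ratios of genes with 1 to 3 counts in a group have exact 95% counting intervals, and a group at 0 was set to a floor of 3 counts.

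Expected counts were rounded and tested with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr on the 4 groups, which left 13196; 13191 symbols had 0 counts in all libraries. TMM factors, robust quasi-likelihood dispersions and quasi-likelihood F tests were used, with all 12 libraries in a single fit with 1 mean per group and 8 residual degrees of freedom. The 5 comparisons were KKO against WT at 24 h, the same at 48 h, the difference between those effects (interaction), and 48 h against 24 h in WT and in KKO. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all tested genes. All tests were 2-sided. On simulated data with 200 changed genes per comparison, the fit recovered 82 and 82% of 2-fold changes and 14 and 12% of 1.2-fold changes at 24 h and 48 h, with the wrong sign in 0; 5.22 and 8.70% of calls were false. For the interaction it recovered 84% of 2-fold and 2% of 1.2-fold changes. All 5 simulated lists of raised genes and 0 of unchanged genes were found. Genes were simulated independently of each other, so this gives no rate of false list calls where the genes of a list vary together.

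Before the data were examined, the tests, the alternatives, 36 gene lists and the rule for naming genes were fixed. The lists cover 23 themes of biology, 10 other cell types and 3 sample checks, written from textbook knowledge; 603 of their 628 genes were in the file and 541 were tested. A list was tested where at least 3 members passed the filter (32 lists), with limma 3.58.1 camera on log2 CPM (prior count 2), a preset correlation of 0.01 and adjustment over the lists of a comparison. Each test was repeated with an estimated correlation and with fry. A list's members were also adjusted over the list alone. Neutrophil, platelet and stroma markers had 2, 1 and 2 tested members and no list test.

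The named genes are Keap1 and Nfe2l2; for each genotype effect the 10 largest rises and 10 largest falls among called genes with a mean of at least 2 CPM and all KKO libraries on one side of all WT libraries; 6 and 6 likewise for each time effect; and for the interaction 5 and 5 with the smallest p, without predicted or unnamed genes. From each list of biology come up to 4 called members with the largest change, or the member with the smallest p. Some genes that the rule names are not reported here. Across time, deviations from the group means of same-numbered libraries correlated at 0.126, 0.103 and 0.343 in WT, all over 0.1, and at 0.0287, 0.0852 and 0.0408 in KKO; the labels do not say what the numbers mark. Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom, no low-count filter or a stricter one (1 CPM in 6 libraries), only the 6 libraries compared, replicate numbers as a block, stricter thresholds (adjusted p under 0.01, or a 2-fold change), and leaving out each library. Added after seeing the data were the male share of each library, read from Y-linked transcripts, as a covariate, and a fit without the 2 libraries that held both Xist and Y-linked transcripts.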

Results

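RNA was sequenced from mouse naive CD4+ T cells that had been activated in culture with antibodies to CD3 and CD28. The cells were wild type (WT) or lacked Keap1 (Keap1 knockout, KKO), and RNA was taken after 24 h or 48 h of activation. Each of the 4 groups had 3 libraries, so 12 libraries were compared. Gene totals ran from 17786532 to 32607675 expected counts per library. Their means, in units of M (mega), were 29.4 ± 2.82 M (SD, n = 3) in WT at 24 h and 25.3 ± 2.72 M (SD, n = 3) in KKO at 24 h. At 48 h they were 20.5 ± 2.09 M (SD, n = 3) in WT and 19.9 ± 1.86 M (SD, n = 3) in KKO. The labels do not say whether libraries of a group came from separate mice or separate cultures. Sex-linked transcripts, given below, show cells of both sexes in each group, so not all cells of a group came from the same mouse. The p-values here measure the spread between these libraries, which includes that difference and may otherwise be technical. Intervals on counts cover counting error only.

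The libraries did not all carry the same sex-linked transcripts. In WT, replicates 1 and 2 held Xist, the RNA of the inactive X chromosome, with at most 1 count of the Y-linked Ddx3y. Replicate 3 held Y-linked transcripts with at most 6 counts of Xist, at both times. In KKO, replicate 2 held Xist at both times, while replicate 3 at 24 h and replicate 1 at 48 h held Y-linked transcripts. KKO replicate 1 at 24 h and KKO replicate 3 at 48 h held both, with Xist at 76.2 and 105 CPM (counts per M of library total) and the Y-linked genes together at 101.8 and 121.9 CPM. The readings of KKO replicates 1 and 3 thus exchange between the times, while those of KKO replicate 2 and of the WT replicates stay. The first principal component carried 72.8% of the variance and parted the times. Group means along it were -58.8 in WT and -47.8 in KKO at 24 h, then 37.8 in WT and 68.9 in KKO at 48 h. At 48 h the libraries also lay apart by sex reading: WT replicates 1 and 2, with Xist, stood at 29.5 and 35.9 and replicate 3 at 47.9, while KKO replicate 2, with Xist only, stood at 53.9 and replicates 1 and 3 at 79.4 and 73.4.

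**Figure D1:**
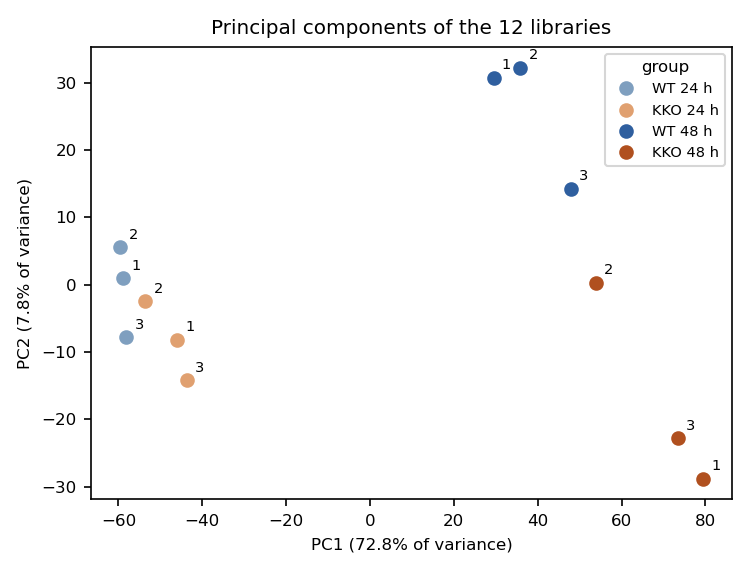
Principal components 1 (x axis, 72.8% of variance) and 2 (y axis, 7.82% of variance) of log2 CPM over the tested genes, 1 point per library with its replicate number beside it. The 24 h and 48 h libraries lie apart along the x axis, and at each time the KKO mean lies to the right of the WT mean.

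Keap1, which encodes the adaptor that marks the transcription factor Nrf2 for degradation, was the targeted gene. It lies on chromosome 9 at 21229730 to 21239332 (mouse build mm10). Its level fell from 107 ± 1.48 CPM in WT to 16.6 ± 0.906 CPM in KKO at 24 h (SD, n = 3), 6.45-fold lower, with a log2 fold change of -2.69 ± 0.06 (SE, adjusted p = 6.3e-13). At 48 h it fell from 126 ± 5.16 to 21.2 ± 1.21 CPM (SD, n = 3), 5.95-fold lower, with a log2 fold change of -2.57 ± 0.06 (SE, adjusted p = 1.22e-12). Every KKO library was below every WT library at its time. The labels do not say which exons were deleted. Nfe2l2, the gene of Nrf2, had log2 fold changes of -0.01 (adjusted p = 0.999) at 24 h and 0.03 (adjusted p = 0.768) at 48 h. Its level was 29.1 CPM in WT and 29.0 CPM in KKO at 24 h, and 39.0 and 39.8 CPM at 48 h. Of the 68 tested genes within 5 Mb of Keap1, edgeR called 0 at 24 h, 4 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0. At 48 h edgeR called 13 of them, 19.1%, against 25.9% of other genes.

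**Figure D2:**
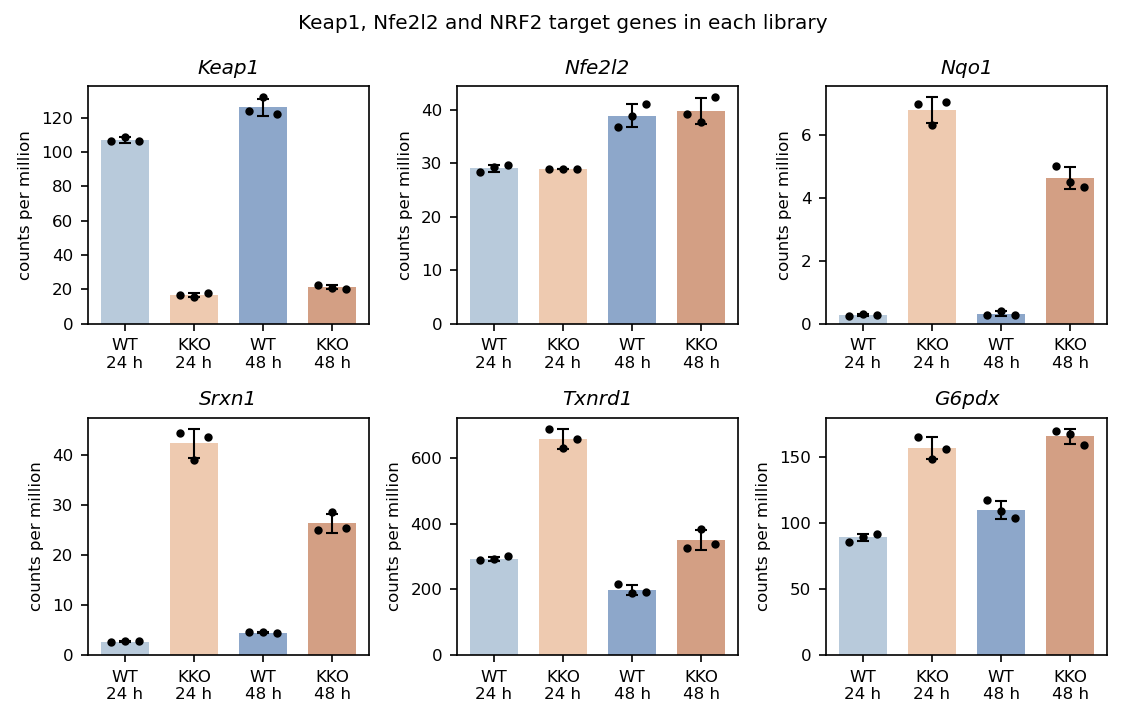
Levels in CPM (y axis) of Keap1, Nfe2l2, Nqo1, Srxn1, Txnrd1 and G6pdx in the 4 groups. Bars are means, error bars are SD and points are libraries (n = 3 per group); Keap1 is lower and Nqo1 and Srxn1 are higher in every KKO library than in every WT library at the same time.

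The comparison of KKO with WT at 24 h asks what loss of Keap1 changes early in activation. Nqo1, a quinone reductase and a classic Nrf2 target, was 23.7-fold higher in KKO, at 6.80 ± 0.413 against 0.281 ± 0.0293 CPM (SD, n = 3). Srxn1, which encodes sulfiredoxin, was 15.6-fold higher, at 42.4 ± 2.89 against 2.71 ± 0.165 CPM (SD, n = 3). The log2 fold changes were 4.56 ± 0.20 (SE, adjusted p = 3.21e-09) for Nqo1 and 3.97 ± 0.09 (SE, adjusted p = 6.3e-13) for Srxn1. Among called genes with a mean of at least 2 CPM and no overlap between KKO and WT libraries, other large rises were Efna5 (3.0 ± 0.59), the cytokine gene Il24 (3.0 ± 0.62), the retinol transporter gene Stra6 (2.46 ± 0.22), the dicarboxylate transporter gene Slc13a3 (2.24 ± 0.25), Ttc39c (2.01 ± 0.31), Il1rn (1.91 ± 0.40), Batf3 (1.89 ± 0.27) and Rai14 (1.88 ± 0.41), as log2 fold change with SE. Apart from Keap1, the largest falls within these limits were smaller: Spin2c -1.14 ± 0.18, Dapl1 -0.89 ± 0.13, Ms4a4b -0.88 ± 0.16, Rgl1 -0.84 ± 0.15, Fam84a -0.83 ± 0.21, Tbc1d30 -0.77 ± 0.11, Itm2a -0.63 ± 0.12, Adamts6 -0.63 ± 0.13 and Dusp6 -0.62 ± 0.09.

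In all, 307 of 13196 genes were called at 24 h, 250 higher and 57 lower in KKO, and 71 of them changed at least 2-fold. The count was 107 without the 2 libraries that held both kinds of sex-linked transcript, 488 with DESeq2 and 524 when only the 6 libraries of 24 h were fitted. It was 138 without WT replicate 2 at 24 h, 152 without WT replicate 3 at 24 h, 176 without KKO replicate 1 at 24 h, 132 without KKO replicate 3 at 24 h and 505 without KKO replicate 2 at 48 h.

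Nrf2 target genes, which code for enzymes of redox and drug metabolism, rose together at 24 h: 14 of 34 tested members rose and 20 were not called, and 20 rose and 1 fell when adjusted over the list alone (median log2 fold change 0.39, camera adjusted p = 4.93e-24; adjusted p = 0.0247 with an estimated correlation). The ferritin light chain gene Ftl1 (log2 fold change 1.32) and the thioredoxin reductase gene Txnrd1 (1.17) followed Nqo1 and Srxn1. Of 14 genes of the pentose phosphate pathway and NADPH supply, 3 rose and 11 were not called, and 5 rose when adjusted over the list alone (camera adjusted p = 0.00450; adjusted p = 0.372 with an estimated correlation). Those 3 were G6pdx (0.82) and H6pd (0.40), both glucose-6-phosphate dehydrogenases, and Taldo1 (0.27). Iron and heme genes had 2 of 14 higher, Ftl1 and Fth1 (0.37), and 12 not called, with 4 higher when adjusted over the list alone (camera adjusted p = 0.00411; adjusted p = 0.188 with an estimated correlation).

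The series title asks about glucose and glutamine metabolism. At 24 h edgeR called 0 of 24 genes of glycolysis and glucose uptake; 3 had an unadjusted p under 0.05, DESeq2 called 1 and limma-voom 0 (median log2 fold change 0.06, camera adjusted p = 0.0770). The smallest p was that of Hk2, the inducible hexokinase, at 0.24 (adjusted p = 0.123). Of 26 genes of glutamine and glutamate metabolism edgeR, DESeq2 and limma-voom each called 0, and 1 had an unadjusted p under 0.05: the glutaminase gene Gls2, at 0.43 (adjusted p = 0.217). The list had a camera adjusted p of 0.791. None of the 24 or the 26 was called when adjusted over its list alone. Of 25 tricarboxylic acid cycle genes all 3 tools called 0, 1 with an unadjusted p under 0.05 (Idh3b, -0.14; camera adjusted p = 0.213). Of 55 nuclear genes of oxidative phosphorylation all 3 tools called 0, with 0 at an unadjusted p under 0.05. The list stood lower as a whole (median -0.03, camera adjusted p = 0.0307; adjusted p = 0.803 with an estimated correlation). Among ATF4 and amino acid stress genes 1 of 27 rose, Atf3 at 1.0, and 26 were not called. Adjusted over the list alone 4 rose (camera adjusted p = 0.00481; adjusted p = 0.511 with an estimated correlation). Of cholesterol and lipid synthesis genes 2 of 26 rose, the desaturase genes Scd1 (1.36) and Scd2 (0.65). Adjusted over the list alone 3 rose (camera adjusted p = 7.08e-07; adjusted p = 0.397 with an estimated correlation). The hypoxia list had 1 of 18 higher, Bhlhe40 at 0.47, and 2 when adjusted over the list alone (camera adjusted p = 0.00757; adjusted p = 0.676 with an estimated correlation).

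Genes of mitosis rose in KKO at 24 h: 12 of 25 rose and 13 were not called, and 22 rose when adjusted over the list alone (median log2 fold change 0.36, camera adjusted p = 3.03e-20; adjusted p = 0.110 with an estimated correlation). Ube2c, Plk1, Hmmr and Nusap1, which act in spindle assembly or cyclin destruction, each had a log2 fold change of 0.53. Of 28 genes of DNA replication, edgeR, DESeq2 and limma-voom each called 0 and 1 had an unadjusted p under 0.05, Ccne1 at 0.25 (camera adjusted p = 0.896). Apoptosis and p53 response genes had 2 of 19 lower, Bbc3 (-0.40) and Zmat3 (-0.31), with 3 lower when adjusted over the list alone (camera adjusted p = 0.00928; adjusted p = 0.0696 with an estimated correlation). Of the interferon response, 25 genes gave 0 calls in all 3 tools and 2 at an unadjusted p under 0.05. Oasl2 had the smallest p at 1.24 (adjusted p = 0.158), and the list a camera adjusted p of 0.405. Ribosome biogenesis (20 genes, 0 at an unadjusted p under 0.05), endoplasmic reticulum stress (15 genes, 1) and the heat shock response (13 genes, 2) gave 0 calls in edgeR, DESeq2 and limma-voom, with camera adjusted p of 0.380, 0.844 and 0.305. Their smallest p-values were those of Fbl (-0.08), Xbp1 (0.21) and Hspa1b (0.52), and 2 heat shock genes were higher when adjusted over the list alone.

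Type 2 helper T cell genes, which include cytokines of allergic and antiparasite responses, were higher at 24 h. Of 13 Th2 effector genes 7 rose and 6 were not called, and 10 rose when adjusted over the list alone (median log2 fold change 0.91, camera adjusted p = 6.78e-17; adjusted p = 0.00333 with an estimated correlation). Il24 (3.0), Il9 (2.39), Il3 (1.34) and the chemokine receptor gene Ccr4 (0.94) were the largest. Th1 effector genes had 2 of 15 higher, the granzyme gene Gzmb (1.44) and Il12rb2 (0.80), and 3 when adjusted over the list alone (camera adjusted p = 9.13e-06; adjusted p = 0.0574 with an estimated correlation). Th17 genes had 1 of 10 lower, Irf4 at -0.22, and 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.229). Il17a and Il23r of that list did not pass the low-count filter and were not tested in any comparison. Regulatory T cell genes had 1 of 14 higher, Ikzf4 at 0.71, with 5 when adjusted over the list alone (camera adjusted p = 0.00481; adjusted p = 0.412 with an estimated correlation). Of 26 T-cell activation genes 2 fell, Cd200 and Irf4 (both -0.22), and 24 were not called. When adjusted over the list alone 4 rose and 9 fell (camera adjusted p = 0.0307, downward; adjusted p = 0.316 with an estimated correlation). Naive T cell genes went both ways: Il7r (0.80) and Satb1 (0.60) rose, Dapl1 (-0.89) and Il6st (-0.45) fell and 16 were not called. Adjusted over the list alone 2 rose and 7 fell (camera adjusted p = 0.0105, downward; adjusted p = 0.205 with an estimated correlation).

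Markers of other lymphocytes moved with these groups at 24 h. Of 9 B cell genes 5 rose and 4 were not called, and 8 rose when adjusted over the list alone (median log2 fold change 1.09, camera adjusted p = 2.13e-10; adjusted p = 0.0543 with an estimated correlation). All 10 B cell genes in the file, the untested Cr2 among them, summed to 14.9 ± 2.81 CPM in WT and 30.3 ± 4.76 CPM in KKO (SD, n = 3). The dendritic cell list had 3 of 6 higher, all of them antigen presentation genes that B cells also express, and 4 when adjusted over the list alone (camera adjusted p = 6.23e-07; adjusted p = 0.0328 with an estimated correlation). Over its 12 genes in the file the sums were 67.5 ± 1.80 and 101.8 ± 3.98 CPM (SD, n = 3). Among γδ T cell and innate lymphoid genes 1 of 6 rose, Trdc, from 2.89 to 5.80 CPM, and 2 did when adjusted over the list alone (camera adjusted p = 0.00455; adjusted p = 0.205 with an estimated correlation). CD8 T cell and natural killer genes gave 0 calls of 7 each in all 3 tools, 4 and 3 with an unadjusted p under 0.05. Both lists were higher as a whole (medians 0.43 and 0.61, camera adjusted p = 0.00305 and 0.00447; adjusted p = 0.0543 and 0.227 with an estimated correlation). The CD8 T cell and natural killer lists share Gzma, Prf1 and Eomes, so their results are not independent. In WT at 24 h Eomes stood at 35.3 CPM and Crtam at 26.9 CPM, beside Cd8a at 2.16 and Ncr1 at 0.690 CPM. Which cells carried these transcripts was not tested. Macrophage genes gave 0 calls of 6 in all 3 tools, 3 with an unadjusted p under 0.05 (camera adjusted p = 0.762). Erythroid genes (3 tested, camera adjusted p = 0.380), nuclear-retained RNAs (9 tested, 0.578) and sex-linked genes (5 tested, 0.380) gave 0 calls in all 3 tools and 0 at an unadjusted p under 0.05.

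**Figure D3:**
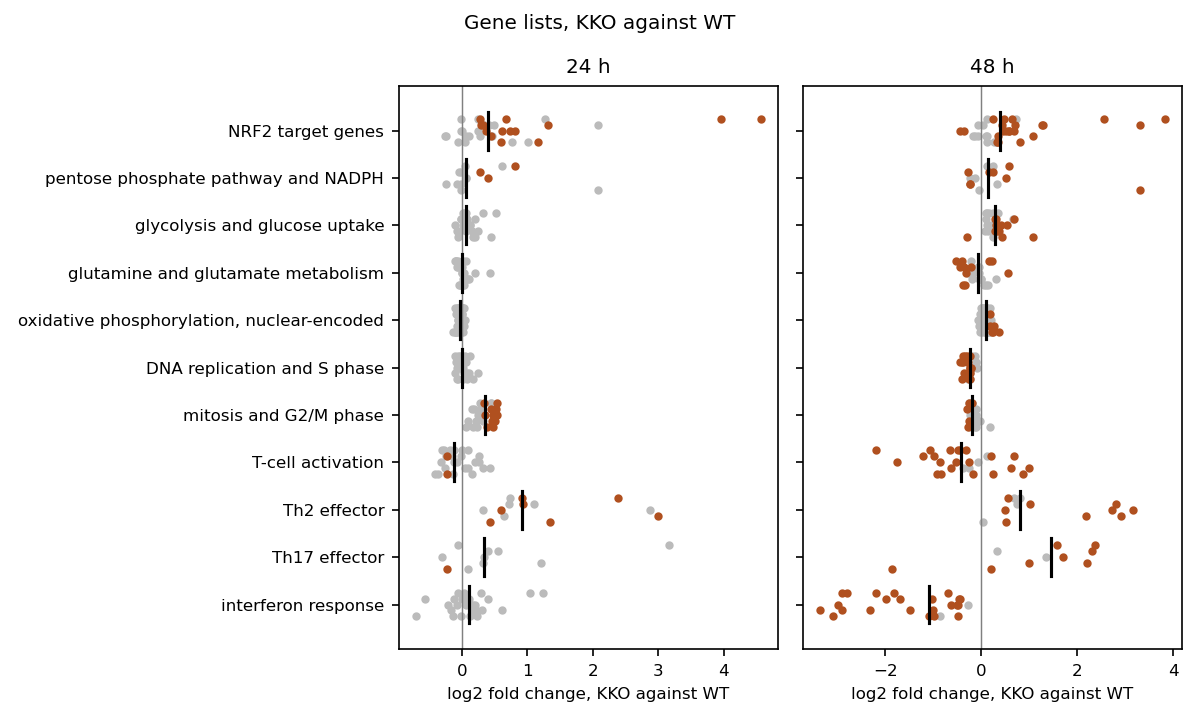
Log2 fold change of KKO against WT (x axis; the range differs between the panels) of each tested member of 11 gene lists at 24 h and 48 h. Orange points were called at an adjusted p under 0.05, grey points were not and black lines are list medians, from -1.08 for the interferon response at 48 h to 1.46 for Th17 genes at 48 h.

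The comparison of KKO with WT at 48 h asks the same after a further day of activation. RefSeq lists Mx1, an interferon response gene, as a transcribed pseudogene, and Mx2 likewise. Mx1 stood at 1.12 ± 0.705 CPM in KKO against 11.2 ± 2.77 CPM in WT, and Oasl2 at 1.38 ± 0.255 against 9.56 ± 2.58 CPM (SD, n = 3). Their log2 fold changes were -3.35 ± 0.38 (SE, adjusted p = 7.98e-05) and -2.78 ± 0.26 (SE, adjusted p = 1.19e-05). Nqo1 was still 14.2-fold higher (3.83 ± 0.22 SE, adjusted p = 9.79e-08), and Il24 reached 83.6 ± 20.1 CPM against 11.1 ± 1.86 CPM (SD, n = 3; 2.92 ± 0.21 SE, adjusted p = 8.82e-06). Among called genes with a mean of at least 2 CPM and all KKO libraries on one side of all WT libraries, the other largest rises were Gipr (3.59 ± 0.57), Timp1 (3.47 ± 0.51), Tnfrsf8, which encodes the activation receptor CD30 (3.03 ± 0.25), Cyp11a1, the first enzyme of steroid hormone synthesis (2.89 ± 0.20), the transcription factor gene Maf (2.81 ± 0.48), Plcd1 (2.80 ± 0.27), Ecm1 (2.73 ± 0.38) and Lilr4b (2.68 ± 0.42). Within the same limits the other largest falls were Pydc3 (-3.55 ± 0.44), Ifi203 (-3.09 ± 0.41), Ms4a4c (-2.79 ± 0.26), Mndal (-2.79 ± 0.43), Cyr61 (-2.62 ± 0.44), Mx2 (-2.58 ± 0.25) and Mpeg1 (-2.56 ± 0.27), as log2 fold change with SE.

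At 48 h 3209 of 13196 genes (24.3%) were called, 1635 higher and 1574 lower in KKO, and 391 of the higher and 170 of the lower changed at least 2-fold. The count was 1386 without the 2 libraries that held both kinds of sex-linked transcript and 1536 when only the 6 libraries of 48 h were fitted. It was 1719 without WT replicate 1, 1697 without WT replicate 2, 1405 without KKO replicate 1, 5362 without KKO replicate 2 and 1659 without KKO replicate 3, all at 48 h. KKO replicate 2 also stood apart at 48 h, with a Spearman's rho of 0.989 and 0.992 to replicates 1 and 3, against 0.996 between those.

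Of 25 interferon response genes 23 fell and 2 were not called at 48 h, and all 25 fell when adjusted over the list alone (median log2 fold change -1.08, camera adjusted p = 3.54e-18; adjusted p = 0.174 with an estimated correlation). Ifit3 (-2.98) and Rtp4 (-2.90) followed Mx1 and Ifi203. In the same libraries 9 markers of macrophages and of plasmacytoid and conventional dendritic cells summed to 0.322 CPM in WT, of which Xcr1 gave 0.224 CPM. Other macrophage genes that fell were Mpeg1, from 11.8 CPM in WT to 2.04 CPM in KKO, and Ctss, from 69.2 to 45.1 CPM. Cd68 (2.85 CPM in WT and 6.28 CPM in KKO) and Fcer1g (0.546 and 1.37 CPM) stood higher in KKO. The tested interferon genes summed to 2450 CPM in WT and 1497 CPM in KKO.

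T-cell activation genes were lower in KKO at 48 h: 16 of 26 fell, 6 rose and 4 were not called, and 17 fell and 6 rose when adjusted over the list alone (median log2 fold change -0.42, camera adjusted p = 0.000261; adjusted p = 0.174 with an estimated correlation). The chemokine gene Xcl1 (-2.19), Il2 (-1.76), the early receptor-response gene Nr4a3 (-1.20) and Cd69 (-1.06) fell most. Of 28 DNA replication genes 19 fell and 9 were not called, 24 when adjusted over the list alone (median -0.24, camera adjusted p = 1.16e-07; adjusted p = 0.500 with an estimated correlation). Mcm10 (-0.44), Chaf1b (-0.41) and Tyms (-0.38) were among them. Of 20 ribosome biogenesis genes 12 fell and 8 were not called, 15 when adjusted over the list alone (median -0.30, camera adjusted p = 5.84e-05; adjusted p = 0.500 with an estimated correlation). They included Polr1b (-0.46), Nolc1 (-0.45), Dkc1 (-0.43) and Nop58 (-0.37). Mitosis genes had 5 of 25 lower and 20 not called, a smaller share called than the 24.3% of all tested genes. The 5 included Kif11 (-0.28), Cenpe (-0.27), Kif23 and Ccna2 (both -0.25). Adjusted over the list alone edgeR called 0 of the 25 (median -0.20, camera adjusted p = 0.000693; adjusted p = 0.552 with an estimated correlation).

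Glycolysis genes rose at 48 h: 11 of 24 rose, 1 fell and 12 were not called, with 12 higher and 1 lower when adjusted over the list alone (median log2 fold change 0.28, camera adjusted p = 0.000172; adjusted p = 0.500 with an estimated correlation). They included the aldolase gene Aldoc (1.09), the phosphofructokinase gene Pfkm (0.69), Pfkfb4 (0.54) and Gpi1 (0.42). Glutamine and glutamate genes went both ways, with 3 of 26 higher, 8 lower and 15 not called, and 3 higher and 11 lower when adjusted over the list alone (median -0.06, camera adjusted p = 0.172). Gls2 rose (0.57), while the mitochondrial glutamate carrier gene Slc25a22 (-0.53), the purine synthesis gene Pfas (-0.45) and the glutamine transporter gene Slc1a5 (-0.39) fell. Of 34 Nrf2 targets 20 rose, 2 fell and 12 were not called, with 21 higher and 2 lower when adjusted over the list alone (median 0.40, camera adjusted p = 4.05e-09; adjusted p = 0.174 with an estimated correlation). The malic enzyme gene Me1 (3.32), Srxn1 (2.55) and Ftl1 (1.29) followed Nqo1. Pentose phosphate and NADPH genes had 5 of 14 higher and 3 lower, G6pdx at 0.59, H6pd at 0.51 and Mthfd1 at -0.27 (camera adjusted p = 0.192). Iron and heme genes had 5 of 14 higher and 1 lower, with Hmox1 at 1.26, Blvrb at 0.70 and Fth1 at 0.68 (camera adjusted p = 0.0690). These lists had 6 higher and 4 lower, and 5 higher and 1 lower, when adjusted over the list alone.

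Other metabolic and stress lists were mixed at 48 h, when 24.3% of all tested genes were called. The oxidative phosphorylation, tricarboxylic acid cycle, ATF4 and heat shock lists had a smaller share of members called than that. The hypoxia list had 8 of 18 higher, 1 lower and 9 not called, 11 and 1 when adjusted over the list alone (median log2 fold change 0.47, camera adjusted p = 0.000731; adjusted p = 0.535 with an estimated correlation). Adm (1.13), Ero1l (1.11), Ddit4 (0.86) and Mxi1 (0.66) rose most. Oxidative phosphorylation genes had 6 of 55 higher, Ndufa6 (0.37) and Ndufb3 (0.27) among them, and 2 when adjusted over the list alone (median 0.10, camera adjusted p = 0.000693; adjusted p = 0.647 with an estimated correlation). Of 15 endoplasmic reticulum stress genes 6 rose, Sdf2l1 (0.33) and Pdia6 (0.26) among them, with 7 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0117; adjusted p = 0.500 with an estimated correlation). Of 26 cholesterol and lipid genes 9 fell and 1 rose, 11 and 1 when adjusted over the list alone (median -0.19, camera adjusted p = 0.00460; adjusted p = 0.647 with an estimated correlation). Idi1 (-0.57), Dhcr7 (-0.45) and Cyp51 (-0.40) fell and the elongase gene Elovl6 (0.51) rose. Tricarboxylic acid cycle genes had 3 of 25 higher and 1 lower (Pcx 0.89, Suclg1 0.49, Cs 0.16 and Dlst -0.25; camera adjusted p = 0.321). ATF4 genes had 4 of 27 higher and 2 lower, with Vldlr at 0.68, Ddit3 at 0.44 and Slc7a1 at -0.41 (median -0.06, mean 0.06, camera adjusted p = 0.872). Adjusted over the list alone they had 2 higher and 1 lower each. Of 19 p53 response genes 3 rose and 6 fell (Cdkn1a 0.92, Bcl2 0.59, Perp -0.84 and Fas -0.36; camera adjusted p = 0.321). Of 13 heat shock genes Dnaja1 (-0.24) and Hspa8 (-0.22) fell (median 0.03, mean -0.04, camera adjusted p = 0.688).

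Of 13 Th2 genes 9 rose and 4 were not called, 10 when adjusted over the list alone (median log2 fold change 0.81, camera adjusted p = 5.92e-08; adjusted p = 0.0444 with an estimated correlation). Il5 stood at 3.17 beside Il24, Maf and Ecm1. Of 10 Th17 genes 7 rose, 1 fell and 2 were not called, 7 and 1 when adjusted over the list alone (median 1.46, camera adjusted p = 0.000818; adjusted p = 0.189 with an estimated correlation). Il21 (2.37), Il1r1 (2.30) and Il22 (2.20) rose, and the chemokine receptor gene Ccr6 fell (-1.85). Il17a and Il23r stayed below the low-count filter, so the Th17 values do not include them. Regulatory T cell genes had 8 of 14 higher and 1 lower, 9 and 1 when adjusted over the list alone (median 0.55, camera adjusted p = 0.000601; adjusted p = 0.468 with an estimated correlation). The cytokine gene Il10 (3.46), Entpd1 (1.54), Ctla4 (0.87) and Il2ra (0.69) rose most. Of 15 Th1 genes 7 fell and 3 rose, 8 and 4 when adjusted over the list alone (median -0.55, camera adjusted p = 0.113). Eomes (-1.64), Il18rap (-1.20) and Ccl3 (-0.98) fell and Hlx (2.18) rose. Naive T cell genes had 7 of 20 higher and 6 lower, with Dapl1 at -1.51, Il7r at 1.29, Igfbp4 at 1.22 and Klf3 at -1.13 (median 0.00, mean 0.07, camera adjusted p = 0.925, downward), and 8 higher and 7 lower when adjusted over the list alone.

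B cell markers stayed higher in KKO at 48 h beside these groups, with 8 of 9 called and 8 when adjusted over the list alone (median log2 fold change 1.21, camera adjusted p = 1.38e-05; adjusted p = 0.189 with an estimated correlation). With the untested Cr2 they summed to 19.3 ± 2.56 CPM in WT and 47.0 ± 4.08 CPM in KKO (SD, n = 3). The dendritic cell list had 4 of 6 higher (median 0.82, camera adjusted p = 0.0111; adjusted p = 0.245 with an estimated correlation). The γδ T cell and innate lymphoid list had 4 of 6 (median 1.23, camera adjusted p = 0.00207; adjusted p = 0.245 with an estimated correlation). Both tested neutrophil genes rose, Ly6g from 0.113 CPM in WT to 2.30 CPM in KKO and Cxcr2 from 2.11 to 4.53 CPM, while S100a8 was at 0.0158 CPM in WT and 0 in KKO and S100a9 at 0 in both. CD8 T cell genes had 4 of 7 higher and 2 lower (camera adjusted p = 0.553). Natural killer genes had 2 higher and 2 lower of 7 (median -0.05, mean 0.24, camera adjusted p = 0.986). Macrophage genes had 2 higher and 2 lower of 6 (median 0.17, mean -0.06, camera adjusted p = 0.925). Erythroid genes gave 0 calls of 3 in edgeR and limma-voom and 1 in DESeq2, with 2 at an unadjusted p under 0.05 (camera adjusted p = 0.0879).

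The calls at 24 h and 48 h overlapped in 191 genes, 180 of them in the same direction: 144 were higher at both times, where 31.0 would be expected by chance, and 36 were lower at both, where 6.80 would be. The other 11 went in opposite directions. Of these 9 were higher at 24 h and lower at 48 h (29.8 expected), and 2 the reverse (7.06 expected). These expectations take every gene as equally likely to be called, although both comparisons shared a single fit. Adarb1, an RNA-editing enzyme gene, was lower at 24 h (-0.50) and higher at 48 h (0.92), as was Irf4 (-0.22 and 0.20). Klf6 (0.57 and -0.49), Plaur (0.95 and -0.55), Zbtb32 (0.60 and -0.22), Irf5 (0.48 and -0.31), Birc5 (0.34 and -0.20), Cenpe (0.39 and -0.27), Clic4 (0.37 and -0.29), Kif4 (0.29 and -0.22) and Serpinb6b (0.41 and -0.24) were higher at 24 h and lower at 48 h. Those genes, apart from Adarb1, Klf6, Irf4 and Cenpe, were chosen after their values were seen. Of the 307 genes called at 24 h, 252 (82.1%) had the same sign at 48 h, and across all tested genes, which are not independent replicates, Pearson's r was 0.257 and Spearman's rho 0.186. The 180 became 86 without WT replicate 2, 96 without WT replicate 3, 103 without KKO replicate 1 and 80 without KKO replicate 3, all at 24 h.

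The interaction asks whether the effect of Keap1 loss differed between the times. Oasl2 had a log2 interaction of -4.03 ± 0.48 (SE, adjusted p = 0.000813), and Srxn1 one of -1.41 ± 0.13 (SE, adjusted p = 0.000148), since its rise was smaller at 48 h. Klf6 (-1.05 ± 0.10), Gbp10 (-1.43 ± 0.15) and Plagl1 (-1.35 ± 0.15) were also negative, and Adarb1 (1.42 ± 0.13), Mapkapk2 (0.64 ± 0.09), St3gal1 (0.73 ± 0.10), Slc25a30 (0.79 ± 0.11) and Irf2bpl (0.88 ± 0.13) positive. For Keap1 it was 0.11 ± 0.08 (SE, adjusted p = 0.432).

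Of the interferon list 20 of 25 genes had a negative interaction call and 23 did when adjusted over the list alone (median -1.31, camera adjusted p = 6.94e-21; adjusted p = 0.186 with an estimated correlation). Of mitosis genes 18 of 25 were negative, 24 when adjusted over the list alone (median -0.55, camera adjusted p = 8.37e-15; adjusted p = 0.409 with an estimated correlation). Ube2c (-0.76), Plk1 (-0.75), Nusap1 (-0.71) and Cdc20 (-0.70) led them. Th1 genes had 7 of 15 negative, 9 when adjusted over the list alone (median -0.77, camera adjusted p = 1.53e-05; adjusted p = 0.186 with an estimated correlation). T-cell activation genes had 8 of 26 negative and 2 positive, 14 and 5 when adjusted over the list alone (median -0.34, camera adjusted p = 0.00378; adjusted p = 0.409 with an estimated correlation). Cholesterol and lipid genes had 5 of 26 negative, 15 when adjusted over the list alone (median -0.38, camera adjusted p = 2.07e-07; adjusted p = 0.705 with an estimated correlation), with Scd1 at -1.51. DNA replication had 1 of 28 negative, Chaf1b at -0.45, and 6 when adjusted over the list alone (median -0.24, camera adjusted p = 6.85e-07; adjusted p = 0.705 with an estimated correlation). Th17 genes had 4 of 10 positive and 1 negative, 5 and 1 when adjusted over the list alone (median 0.83, camera adjusted p = 0.0179; adjusted p = 0.555 with an estimated correlation). They included Ahr (2.02), Batf (0.67) and Ccr6 (-1.95), while Il17a and Il23r were not tested.

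Glycolysis genes had 1 of 24 positive, Pfkm at 0.69, and 1 when adjusted over the list alone (median 0.16, camera adjusted p = 0.00989; adjusted p = 0.705 with an estimated correlation). Glutamine genes had 1 of 26 negative, Slc25a22 at -0.55, and 1 when adjusted over the list alone (camera adjusted p = 0.154). Nrf2 targets had 1 of 34 positive and 2 negative, 5 and 11 when adjusted over the list alone (camera adjusted p = 0.275). Oxidative phosphorylation gave 0 calls of 55 in edgeR and limma-voom, 2 in DESeq2 and 11 at an unadjusted p under 0.05 (median 0.13, camera adjusted p = 1.53e-05; adjusted p = 0.705 with an estimated correlation). Ribosome biogenesis gave 0 calls of 20 in all 3 tools and 8 at an unadjusted p under 0.05 (median -0.28, camera adjusted p = 0.00104; adjusted p = 0.705 with an estimated correlation). Endoplasmic reticulum stress had 1 of 15 positive, Sdf2l1 at 0.31, and 2 when adjusted over the list alone (median 0.12, camera adjusted p = 0.0303; adjusted p = 0.705 with an estimated correlation). B cell markers gave 0 calls of 9 in all 3 tools and 0 at an unadjusted p under 0.05. Eomes, with a called log2 interaction of -2.04, is also a member of the natural killer and CD8 T cell lists.

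The interaction gave 552 called genes, 193 positive and 359 negative. It gave 54 without the 2 libraries that held both kinds of sex-linked transcript, 1470 with the male share of each library as a covariate and 1120 with DESeq2. At 24 h, leaving out WT replicate 1, 2 or 3 gave 361, 212 or 197 and KKO replicate 1, 2 or 3 gave 229, 316 or 232; at 48 h, WT replicate 1 or 2 gave 264 or 143 and KKO replicate 1, 2 or 3 gave 221, 3217 or 175.

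**Figure D4:**
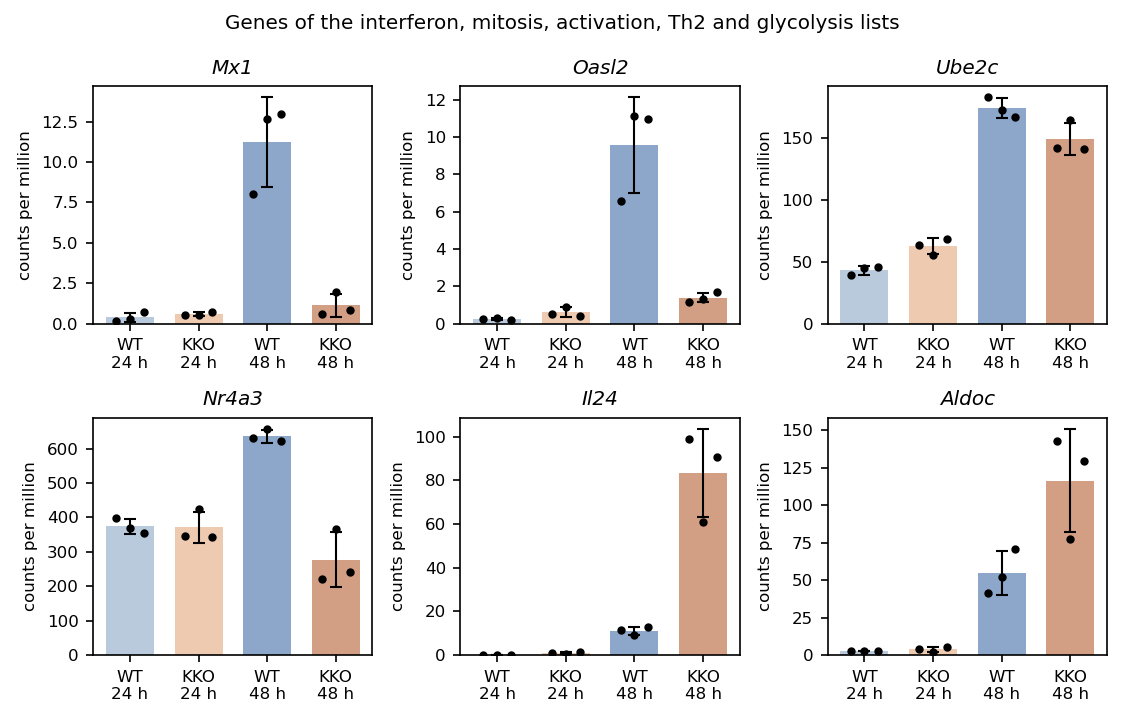
Levels in CPM (y axis) of Mx1, Oasl2, Ube2c, Nr4a3, Il24 and Aldoc in the 4 groups, with bars for means, error bars for SD and points for libraries (n = 3 per group). At 48 h Mx1 averages 11.2 CPM in WT and 1.12 CPM in KKO, and Il24 11.1 and 83.6 CPM.

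The comparison of 48 h with 24 h in WT gives the change over a further day of activation, together with any difference in handling between the times. Glucose use and hypoxia genes rose with time: the aldolase gene Aldoc had a log2 fold change of 4.34, the glucose transporter gene Slc2a3 3.91 and the lactate exporter gene Slc16a3 2.70. The transglutaminase gene Tgm2 (8.07 ± 0.59), the lipoprotein receptor gene Vldlr (7.76 ± 0.37) and the glycogen phosphorylase gene Pygl (6.94 ± 0.46) rose most among genes with a mean of at least 2 CPM and more than 2 counts in the 24 h group, as log2 fold change with SE (n = 3). H2-Q10 went from 1 to 626 counts over the group, a ratio of 892 after scaling to library totals (95% counting interval 159.5 to 35286), Osr2 from 2 to 272 counts (194, 53.1 to 1608) and Stc1 from 2 to 248 counts (177, 48.4 to 1467). Among genes with a mean of at least 2 CPM and no overlap between the times, and apart from Sssca1, Rpph1 (-3.66 ± 0.37), Il1a (-3.37 ± 0.21), the activity-induced transcription factor gene Npas4 (-3.08 ± 0.28), Spin2c (-2.90 ± 0.21) and Ak7 (-2.89 ± 0.21) fell most.

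Of the lists, 21 of 24 glycolysis genes rose and 1 fell in WT (median log2 fold change 1.0, camera adjusted p = 3.64e-07; adjusted p = 0.699 with an estimated correlation), with the same counts when adjusted over the list alone. Hypoxia genes had 17 of 18 higher and 1 lower (median 1.76, camera adjusted p = 7.21e-07). ATF4 genes had 24 of 27 higher, with Asns at 2.82 (median 0.86, camera adjusted p = 2.71e-09). Interferon genes had 20 of 25 higher and 2 lower, with Rsad2 at 6.06 and Oasl2 at 5.18 (median 2.41, camera adjusted p = 8.04e-08). Mitosis genes had 24 of 25 higher, with Ccnb2 at 2.73 (median 0.72, camera adjusted p = 2.71e-09). All 28 DNA replication genes fell (median -0.56, camera adjusted p = 2.18e-08), as did all 20 ribosome biogenesis genes (median -0.74, camera adjusted p = 8.20e-08). Th2 genes had 9 of 13 higher (median 1.45, camera adjusted p = 0.000574). Cholesterol genes had 21 of 26 higher and 2 lower (median 0.44, camera adjusted p = 8.53e-06). When adjusted over the list alone ATF4 genes had 25 higher and interferon genes 21, and the other counts were the same. Glutamine genes split, with 10 of 26 higher and 11 lower, 10 and 12 when adjusted over the list alone: Gpt2 (2.28) and Gls2 (1.72) rose and Cad fell (-1.25; median -0.09, mean 0.14, camera adjusted p = 0.989). With an estimated correlation camera called 0 of the 9 lists that passed in WT, the lowest adjusted p being 0.474, with 2 of 32 lists at an unadjusted p under 0.05; fry called 20 lists. Of all tested genes 60.8% were called for time in WT, and most lists of other cells and sample checks held a smaller share. Dendritic cell genes had 4 of 6 higher and 1 lower (camera adjusted p = 0.186), B cell genes 3 of 9 higher (0.391), macrophage genes 2 of 6 higher (0.798) and erythroid genes 2 of 3 lower (0.470), with the same counts when adjusted over the list alone. Nuclear-retained RNAs, a check of RNA quality to which Rpph1 belongs, had 2 of 9 higher and 2 lower, the same when adjusted over the list alone (median -0.37, camera adjusted p = 0.798). Natural killer genes had 2 of 7 higher and 1 lower (camera adjusted p = 0.442), CD8 T cell genes 1 of 7 higher and 2 lower (0.844) and γδ T cell and innate lymphoid genes 1 of 6 higher (0.949), likewise with the same counts over the list alone. Of neutrophil markers 1 of 2 rose, and of stroma markers 2 of 2.

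In KKO the comparison of 48 h with 24 h asks the same without Keap1. Aldoc (4.98) and Slc2a3 (4.37) rose, and the largest rises among genes with a mean of at least 2 CPM were Tgfb3 (8.05 ± 0.60), Selenbp1 (7.66 ± 0.54), Pygl (7.63 ± 0.42), Vldlr (7.19 ± 0.33), H2-Q10 (8.23 ± 0.64) and Hapln4, which went from 2 to 410 counts (ratio 263, 95% counting interval 72.5 to 2183). Xcl1 (-4.73 ± 0.34), Npas4 (-3.71 ± 0.32), Rpph1 (-3.56 ± 0.37), Il1a (-3.39 ± 0.20) and Ak7 (-3.27 ± 0.23) fell most within the same limit, apart from Sssca1, as log2 fold change with SE (n = 3). Sssca1 went from 1774 counts to 0, at least 460-fold lower against a floor of 3 counts over the group. At 48 h it was also 0 in WT replicates 2 and 3, and 4.73 CPM in WT replicate 1. Glycolysis genes had 23 of 24 higher and 1 lower (median 1.24, camera adjusted p = 5.86e-07). Hypoxia genes had 17 of 18 higher and 1 lower (median 2.22, camera adjusted p = 2.99e-06). ATF4 genes had 20 of 27 higher and 2 lower, with Asns at 2.74 (median 1.0, camera adjusted p = 3.35e-06). Th2 genes had 11 of 13 higher and 1 lower (median 2.05, camera adjusted p = 0.00137). Mitosis genes had 16 of 25 higher (median 0.29, camera adjusted p = 0.00550). All 28 DNA replication genes (median -0.88, camera adjusted p = 1.47e-09) and all 20 ribosome biogenesis genes (median -1.04, camera adjusted p = 7.63e-08) fell. Interferon genes had 13 of 25 higher and 7 lower (median 0.88, camera adjusted p = 0.230). Cholesterol genes had 16 of 26 higher and 6 lower (camera adjusted p = 0.108). Oxidative phosphorylation genes had 30 of 55 higher and 8 lower (camera adjusted p = 0.0594). Glutamine genes had 9 of 26 higher and 13 lower, with Cad at -1.54 (median -0.09, mean 0.04, camera adjusted p = 0.783). ATF4 genes had 21 higher when adjusted over the list alone, and the counts of the other lists named here were the same. With an estimated correlation camera called 0 of the 7 lists that passed in KKO, the lowest adjusted p being 0.549, with 1 of 32 lists at an unadjusted p under 0.05; fry called 20 lists. The counts of other cells and sample checks that follow stand beside 67.8% of all tested genes called for time in KKO. Dendritic cell genes had 3 of 6 higher and 1 lower, 4 and 1 when adjusted over the list alone (camera adjusted p = 0.294). B cell genes had 4 of 9 higher and 1 lower (0.294), erythroid genes 1 of 3 higher and 2 lower (0.783) and nuclear-retained RNAs 2 of 9 higher and 4 lower (median -1.01, camera adjusted p = 0.702), with the same counts when adjusted over the list alone. Natural killer genes had 4 of 7 higher and 2 lower (camera adjusted p = 0.783), CD8 T cell genes 3 of 7 higher and 2 lower (0.948) and γδ T cell and innate lymphoid genes 2 of 6 higher (0.439), likewise with the same counts over the list alone. Macrophage genes had 2 of 6 higher, 1 when adjusted over the list alone (camera adjusted p = 0.939). Both neutrophil and both stroma markers tested rose.

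With time 8017 genes were called in WT, 4097 higher and 3920 lower, and 8945 in KKO, 4544 higher and 4401 lower; at least 2-fold changes numbered 2028 and 2677. Both genotypes shared 7029 of these calls, 3528 higher in both, where 1411 would be expected by chance, and 3441 lower in both, where 1307 would be, with 60 in opposite directions. These expectations, too, take every gene as equally likely to be called. Across all tested genes Pearson's r of the WT and KKO changes was 0.874 and Spearman's rho 0.870.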

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

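Of the tests below, those of myeloid cells and of the shared time course for the interferon genes, those of KKO cultures being ahead, those on cell shares, the fit with the male share, the thinning at 24 h, the fit without the 2 mixed libraries and the splits that keep the 48 h groups whole were chosen after the result was seen. The genes and lists with a log2 interaction below were picked out because the effect of Keap1 loss differed between 24 h and 48 h by the interaction test (n = 3 libraries per group; edgeR for genes, camera with a preset correlation for lists); the course, the B cell markers (0 of 9 called) and the splits were not. None of the 11 lists kept its call with an estimated correlation, 3 of 32 lists had an unadjusted p under 0.05 there, and fry called 4.

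Interferon response genes were lower in KKO at 48 h and had a median log2 interaction of -1.31. The sexes of the libraries do not account for it: with the male share as a covariate the list median at 48 h was -1.09 and 23 of 25 genes were still lower, and without the 2 libraries holding both Xist and Y-linked transcripts 23 were lower with a median of -1.03. A loss of myeloid or plasmacytoid dendritic cells that carried the interferon transcripts themselves is argued against by 9 of their markers, Lyz2 and the C1q genes among them. These summed to 0.322 CPM in WT beside 2450 CPM of interferon genes. The sum cannot tell whether a few such cells acted on the T cells. Of other macrophage genes Mpeg1 (11.8 to 2.04 CPM) and Ctss (69.2 to 45.1 CPM) were lower in KKO, and Cd68 (2.85 to 6.28 CPM) and Fcer1g (0.546 to 1.37 CPM) higher. A single library is argued against by the fewest lower genes over 12 leave-outs being 23. KKO cultures being ahead cannot be told apart: 18 of the 20 genes that rose with time in WT were lower in KKO at 48 h, but with 23 of 25 lower it had to be at least 18, and a peak followed by a fall was not tested. A weaker interferon response of Keap1-deficient T cells and differences between cultures or mice that the labels do not describe stay open too, and the signal that drives the response in WT was not measured.

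KKO libraries lay further along the course from 24 h to 48 h, on the first component at 48 h from 53.9 (replicate 2, with Xist only) to 79.4 against 29.5 to 47.9 in WT. Across genes, the KKO effect at 24 h correlated with the time effect in KKO (Pearson's r 0.150, Spearman's rho 0.133), and the KKO effect at 48 h with the time effect in WT (r 0.284, rho 0.370), although the shared libraries push both below 0 (simulated r without a genotype effect -0.194 and -0.0998). With every library thinned to 17786532 counts r was 0.158 at 24 h and 0.301 at 48 h, which argues against depth. With the male share as a covariate r was 0.228 at 48 h but 0.0337 at 24 h. The 24 h value lies between the 0 and 0.1 set as bounds, so by that rule the sex mix cannot be told apart. A simulation without a genotype effect gave -0.179 at 24 h with this covariate. Against that reference r was still raised, as it was without the covariate (0.150 against -0.194). The spread of the simulated value was not given, so whether the sex mix accounts for all of r at 24 h stays undecided. KKO cultures may have been ahead, which the tests without a covariate allow, but they were run on the data that gave the idea. A later harvest of the KKO cultures, which the labels would not show, and faster activation without Keap1 both stay open, untested.

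Markers of B cells were higher in KKO at 24 h, and a larger share of B cells may be the source. At 24 h 12 B cell and MHC class II genes, 3 of them shared with dendritic cells, had a common log2 fold change of 0.96 ± 0.07 (SE). Of these 0 lay over 2 SE from it, with H2-Ab1 at 11.3 CPM in KKO. The 12 were chosen after values were seen and leave out Cd74, an antigen presentation gene of the dendritic cell list. Cd74 went from 51.8 ± 0.423 CPM in WT to 74.0 ± 4.67 CPM in KKO at 24 h (SD, n = 3). That is proportionally less than any of the 12, of which Fcmr was lowest at 0.73, so the 0 holds for the chosen 12 only. Isolation of naive CD4+ cells, which the labels name, would remove B cells. At 48 h 5 of the 12 lay over 2 SE from their common value (Cd22, Ebf1, Fcmr, H2-Eb1 and Ms4a1), from Ms4a1 at 0.38 to Fcmr at 1.95. A larger share alone therefore does not give the 48 h values. Whether a lower share of CD4+ cells was the only source at 24 h cannot be told. The B cell median exceeded that of 6 CD8 T cell and macrophage markers by 0.58 ± 0.202 (SE), and by 0.56 ± 0.224 without Cd8b1. Cd8a stood at 0.53 ± 0.24 and Cd8b1 at 0.43 ± 0.13 against 1.09. Markers that the CD4+ cells express too would rise less, so this gap does not decide. Mpeg1, among the 6, stood at 11.8 CPM in WT at 48 h beside Lyz2 at 0.0645 CPM, while Itgam and Ctss were left out for their levels. As a part, a lower share of CD4+ cells stays open too. The rule for the gap was changed after values were seen, and then again: for the 4 macrophage markers alone the gap was 0.55, with an SE of 0.178 from weighted means or 0.253 from medians, and 0.49 ± 0.301 without Cd68, and the CD8 markers were then added.

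Of the 10 splits of the 6 libraries at 24 h, the real one included, only the real split reached its own count (524 genes, highest other 36). Likewise only 1 of 10, the real split, did so at 48 h (1536, highest other 5), for time in WT (8126, highest other 0) and for time in KKO (8380, highest other 0). These splits are too few for a share under 0.05. Every other split also mixes the real groups, so a real difference would widen its spread and lower its calls. The low counts of the other splits are therefore no reference without a difference. For the interaction 3 of 100 splits, the real one among the 3, called at least as many genes as the real one (552), and the highest other called 970. This does not test the interaction, because most drawn splits mix the 48 h libraries and so lose the genotype difference there too. Of the 20 splits that keep the 48 h groups whole, 7 called at least as many, the real split among the 7, and the highest other called 1847. That split keeps the 24 h groups whole too, with the genotypes exchanged at 1 time, so it adds the 2 genotype effects in place of subtracting them. The remaining ones, apart from the real split, mix the 24 h libraries but keep the genotype difference at 48 h. Their counts are therefore no reference without an interaction, and neither set of splits tests it.

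Among single genes with a difference between the times, Adarb1 (1.42), Mapkapk2 (0.64), St3gal1 (0.73), Slc25a30 (0.79) and Irf2bpl (0.88) had positive log2 interactions and Srxn1 (-1.41), Klf6 (-1.05), Gbp10 (-1.43), Plagl1 (-1.35) and Oasl2 (-4.03) negative ones. Of the interferon list, Mx1 (-3.97), Ifi44 (-3.20) and Rtp4 (-2.94) followed Oasl2. Nrf2 targets included Ugdh (0.60) and Nampt (-0.42), glycolysis Pfkm (0.69; list median 0.16), glutamine genes Slc25a22 (-0.55), ATF4 genes Chac1 (-1.03) and Atf3 (-0.98), and the tricarboxylic acid cycle Suclg1 (0.53). The oxidative phosphorylation list had a median of 0.13.

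The DNA replication list had a median of -0.24, with Chaf1b at -0.45, and the mitosis list -0.55, with Ube2c (-0.76), Plk1 (-0.75), Nusap1 (-0.71) and Cdc20 (-0.70). T-cell activation genes had a median of -0.34, with Xcl1 (-2.07), Nr4a3 (-1.19), Cd69 (-0.75) and Nr4a2 (-0.75). Naive T cell genes included Il6ra (1.16), Ccr7 (-0.44) and Foxo1 (0.41). Th1 genes had a median of -0.77, with Eomes (-2.04), Il18rap (-1.54), Ccl3 (-1.38) and Gzmb (-0.96), and Th2 genes included Ecm1 (2.42), Il13 (1.53) and Il3 (-1.31). Th17 genes had a median of 0.83, with Ahr (2.02), Ccr6 (-1.95) and Batf (0.67), and Nrp1 of the regulatory T cell list stood at -1.38. Cholesterol and lipid genes had a median of -0.38, with Scd1 (-1.51), Dhcr7 (-0.55) and Sc5d (-0.48). Perp of the p53 list stood at -1.14, ribosome biogenesis had a median of -0.28 and endoplasmic reticulum stress one of 0.12, with Sdf2l1 at 0.31.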

How the results depend on the processing

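The fits with the male share as a covariate and without the 2 libraries holding both Xist and Y-linked transcripts, and the list tests with a block within genotype, were chosen after seeing the data. The causes of the changes below were not tested, except that stricter thresholds pass fewer genes and left-out libraries leave fewer samples. Keap1 ranged from -2.73 to -2.66 at 24 h and from -2.62 to -2.54 at 48 h over the leave-outs. In place of the 307 genes called at 24 h, DESeq2 called 488, the 6 libraries alone 524, the fit without the 2 mixed libraries 107 (99 of them among the 307), a 2-fold change 71 and an adjusted p under 0.01 128. At 48 h 3209 became 1536 with the 6 libraries alone, 1386 without the 2 mixed libraries (1370 of them among the 3209), 561 with a 2-fold change and 1363 at an adjusted p under 0.01. The interaction's 552 became 1120 with DESeq2, 1470 with the male share, 54 without the 2 mixed libraries, 148 with a 2-fold change and 85 at an adjusted p under 0.01. A 2-fold change left 2028 genes for time in WT and 2677 in KKO. The 180 genes called in 1 direction at both times became 68 at an adjusted p under 0.01.

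Leaving out 1 library gave 132 to 505 genes at 24 h, 1405 to 5362 at 48 h, 143 to 3217 for the interaction, 7245 to 8479 for time in WT, 8262 to 9246 for time in KKO and 80 to 258 for the overlap; the libraries that moved a count are named in the report. Lists called at 24 h numbered 19, 3 with an estimated correlation and 11 with fry; at 48 h 17, and 1 with an estimated correlation; for the interaction 11, 0 and 4; for time in WT 9, 0 and 20; for time in KKO 7, 0 and 20. The glutamine list reversed for time in WT under fry (adjusted p = 0.00582, upward, against a camera adjusted p of 0.989, downward). With the replicate numbers as a block, a replicate block, the counts were 322, 2894, 637, 7844 and 8778 in the order of the comparisons, and a replicate block within genotype gave 931 for the interaction, 7982 for time in WT and 8858 for time in KKO. Across time same-numbered libraries correlated at over 0.1 in WT, where this block left the 9 list calls and changed among named genes only Sssca1, but not in KKO. Pairing by number is not shown in WT either. WT 1 at 24 h correlated at 0.151 with WT 2 at 48 h, against 0.126 with its own number. The highest value, 0.343, was that of WT 3, which held Y-linked transcripts at both times. KKO numbers 1 and 3 may not mark the same cultures at both times, since their sex readings exchange: KKO 1 at 24 h correlated at -0.122 with KKO 3 at 48 h, and KKO 3 at 24 h at 0.170 with KKO 1 at 48 h. Across genotypes the numbers paired the libraries at neither time, and not every library correlated best with its own number. Of 419 values of named genes, 413 kept their side of the threshold with DESeq2, 407 with limma-voom and 315 without the 2 mixed libraries, and 0 called values reversed under any alternative run. On simulated data 1.2-fold changes were mostly missed at this depth and number of libraries.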

Other observations

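The 10 highest genes took 8.02% of the counts in KKO replicate 1 at 48 h and 5.91% in WT replicate 1 at 24 h, the highest and lowest shares of the 12 libraries. Nuclear-retained RNAs, read as a sign of RNA quality, summed to 511 ± 380 CPM in WT and 504 ± 545 CPM in KKO at 24 h and to 392 ± 280 and 236 ± 122 CPM at 48 h (SD, n = 3). That list contains Xist, which follows the sex-linked reading of each library. Erythroid markers summed to 3.41 CPM in WT and 4.69 CPM in KKO at 24 h and to 0.983 and 2.12 CPM at 48 h. Of the stroma and endothelium markers Pecam1 alone stood at 24.0 and 21.6 CPM at 24 h and 34.1 and 39.2 CPM at 48 h, while Col3a1 and Cdh5 were at 0 in every group, so these markers give no level of stroma. Platelet markers summed to 0.859 and 0.988 CPM at 24 h and 0.947 and 1.02 CPM at 48 h.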
